A study of Mus musculus with 14 samples.

How the data were processed

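Liver RNA of 14 C57BL/6 male mouse samples was analysed, 8 from the model group and 6 from the control group. Per the labels' protocols, model mice received lipopolysaccharide (LPS, a bacterial cell wall component) at 10 µg/kg together with D-galactosamine (D-GalN, an amino sugar that is toxic to hepatocytes) at 300 mg/kg by intraperitoneal injection, and control mice received saline. Livers were taken 24 h later, polyadenylated RNA was enriched with oligo(dT) beads, and libraries were sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The labels name separate samples of each group. No label states that each sample is a separate animal or how cages and days were shared, so p-values measure the spread between these samples.

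The deposited values are raw read counts per gene, 1 file per sample, with versioned Ensembl gene identifiers and gene symbols. Reads were aligned with HISAT2 to the mouse genome build GRCm39, per the submitters' processing notes. The aligner version, the counting program, its strand setting and the annotation release are not given in the sources used here. Each deposited file ends with 5 summary lines of the kind that a read counter writes. They cover reads outside genes, ambiguous reads, reads of low alignment quality, unaligned reads and reads aligned to several places. These lines name no gene and were kept out of library totals and tests. They held between 27.4% and 45.6% of all entries of a library. Counts without a stated strand setting cannot separate a gene from an overlapping gene on the other strand, and overlaps in the annotation supplied are named where they concern a gene in the text. Besides those, Abcb11, Cebpa, Cyp2u1, Gclm, Il1b, Mt2, Nags, Sds and Usp2 overlap a gene on the other strand. The summary line of reads aligned to several places held 13.4% to 18.6% of all entries of a library. Members of near-identical families, such as the haemoglobin and major urinary protein genes, can lose or share such reads. They are reported mainly as sums over the class, which do not recover lost reads.

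The files held 55357 genes, and 79 symbols were carried by several identifiers, which were kept apart. Genes with enough counts were kept with filterByExpr of edgeR, which left 12915 genes. Differences were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling factors, a robust quasi-likelihood fit with the group as the only term, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05, and counts are also given for calls of at least 2-fold. Values per library are counts scaled to the library size (CPM), computed with the TMM factors. Log2 CPM used a prior count of 2. Fold changes are model over control, and the standard error (SE) is the log2 fold change divided by the root of the F statistic. Where a group held no count, the fold is given as a lower bound against 3 counts over the group, which is 0.0401 CPM for the controls. Where it held 1 to 3 counts, a ratio is given with an exact 95% Poisson interval. Such intervals and floors cover counting error only.

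There were 34 gene lists with 826 genes, chosen before the data were examined: 19 for functions, 9 for markers of cell types and 6 for blood, other tissues, time of day and RNA state. By symbol, 6 list genes had no row. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. A correlation estimated for each list was the alternative. Camera compares a list with all other genes. Genes named in the text follow a rule that was also fixed beforehand. It takes the 5 largest changes in each direction among called genes with a mean of at least 10 CPM in a group and group ranges that do not overlap, leaving out predicted genes, pseudogenes and receptor segments. It adds up to 2 members in the main direction and 1 in the other of each function list at a mean of at least 5 CPM, 1 member of each other list, and 10 genes fixed by name. This gave 80 genes. Further list members named as examples were chosen after their values were seen.

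Shares of counts in gene classes and distances of libraries from their own group were compared with two-sided exact permutation tests over all 3003 splits of the 14 libraries into 8 and 6, whose smallest possible p is 0.000333. The ribosomal RNA class was added after seeing the data. No pair of libraries of a group agreed within sampling noise: over 43 pairs, the smallest chi-square per degree of freedom was 23.3, for genes with at least 20 counts in a pair. Exonic length and GC content came from the GENCODE annotation supplied for another build, GRCm38, matched by gene identifier for 99.9% of the tested genes. No coordinates of that build are printed.

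The tests were run on simulated counts first. For model against control, counts for 12915 genes were drawn with 225 genes changed. The edgeR test recovered 4% of 50 genes changed 1.5-fold, 34% of 50 changed 2-fold, 92% of 50 changed 4-fold and 92% of 50 changed 8-fold. It made 129 calls, of which 5.43% were false, and none had the wrong sign. In the data 47.9% of the tested genes were called, so the adjusted threshold was less strict there. The simulated recovery therefore does not describe the test on the data. Camera recovered a planted list and called 0 of 20 random lists of independent genes, so this says nothing of lists whose genes vary together.

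Alternatives chosen before the data were examined were other scaling factors (DESeq2 size factors, library totals, upper quartile), DESeq2 1.42.0, limma-voom, other low-count filters, a replicate block, a fit without robust estimation, leaving out the 20 most abundant genes, leaving out each library, and for lists an estimated correlation and fry. Added after seeing the data were an offset for exonic length and GC content, the slope on exonic length as a covariate, and the omission of model 3 and model 4, the model libraries with the highest ribosomal RNA shares. Both also had the highest mitochondrial shares of the model libraries, 20.8% and 14.4%. By definition, both classes include the mitochondrially encoded ribosomal RNAs, so these shares are not independent. Figures were drawn with matplotlib 3.10.9.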

Results

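The series compares livers of mice with acute liver failure, brought on by LPS and D-GalN, with livers of mice injected with saline, 24 h after injection. Its title states an interest in immune-related genes. Total counts in genes ranged from 10329469 to 16639972 in the 8 model libraries and from 7914120 to 14463540 in the 6 control libraries. The number of genes with at least 1 count was 18284 ± 373.5 in model (SD, n = 8) and 16851 ± 544.9 in control (SD, n = 6).

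In the model livers, 32 of 33 genes of NF-kB and cytokine signalling, 17 of 18 neutrophil markers and all 21 immediate early genes were higher. Of 29 genes of bile acid synthesis and transport, 11 were lower and 5 higher, without a call for the list (adjusted p = 0.0846). Of 31 genes of hepatocyte identity and secreted proteins, 3 were higher and 4 lower, a count that depended on the normalization (9 and 5 with the length and GC offset, 1 and 11 with library totals). Of 12915 genes tested, 3437 were higher and 2751 lower in model by edgeR's quasi-likelihood test, 47.9% of those tested. At least 2-fold, 2619 were higher and 1636 lower. The CPM ranges of the groups did not overlap for 3001 genes, 23.2% of those tested, where chance alone gives 0.0666%. Without model 3 and model 4, the model libraries with the most ribosomal RNA, 3476 genes were higher and 2599 lower, and 2636 and 1694 at least 2-fold. With library totals in place of TMM factors, the median fold change of all genes moved from 0.0099 to -0.23 on the log2 scale, and 2533 genes were higher and 3955 lower. Changes below are relative to the TMM scale.

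The first principal component of log2 CPM held 64.6% of the variance and separated the groups. The second held 14.2%, separated libraries within each group, and its loadings correlated with exonic length across genes (Spearman rho -0.55; genes are not independent replicates). The median log2 fold change went from -0.23 in the fifth of genes with the shortest exonic length to 0.28 in the fifth with the longest.

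**Figure D1:**
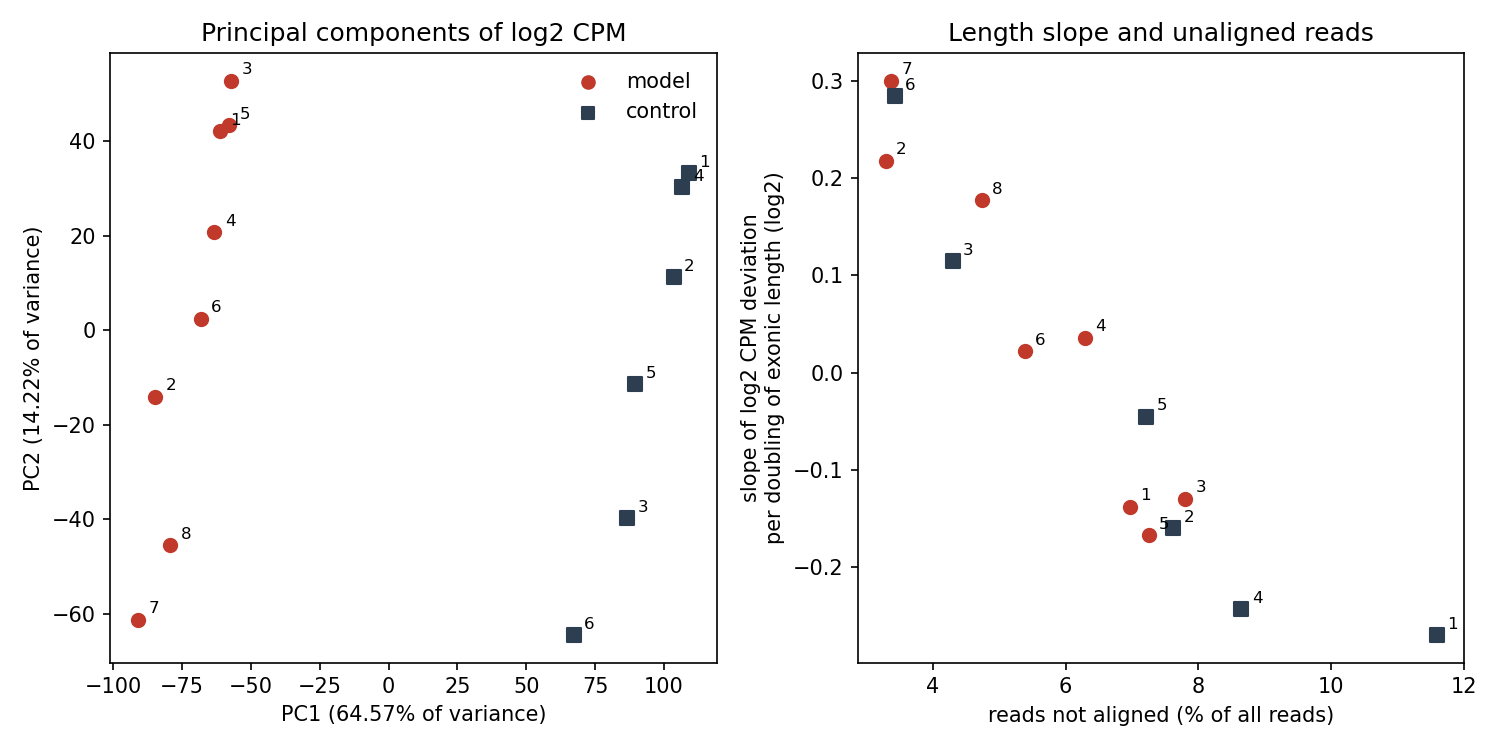
Left, the first and second principal components of log2 CPM for the 8 model (circles) and 6 control (squares) libraries, numbered by replicate; the groups lie apart on the first component. Right, each library's slope of log2 CPM deviation per doubling of exonic length against the percent of reads not aligned; slopes run from -0.269 to 0.300 and are higher where fewer reads were unaligned in both groups.

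The largest increases by the naming rule were in Cxcl2 and Ccl3, chemokines that attract neutrophils and monocytes; Acod1, the enzyme that makes itaconate in activated macrophages; Slfn4, an interferon-inducible gene of myeloid cells; and Ptgs2, the inducible cyclooxygenase. Cxcl2 was at 279 ± 107 CPM in model (SD, n = 8) and had 3 counts in all controls together, a ratio of 6971 with an exact 95% interval from 2385 to 33800. Acod1 was at 164 ± 59.9 CPM with 3 control counts, a ratio of 4083 (exact 95% interval 1397 to 19800). Their fitted log2 fold changes were 12.43 and 11.66, against 13.38 for Cxcl2 without control 5 and 12.68 for Acod1 without control 2. Ccl3 and Ptgs2 had no control count and were at least 1222-fold and 661-fold higher. Slfn4 rose from 0.217 ± 0.162 to 603 ± 218 CPM (log2 fold change 11.52, SE 0.48, adjusted p = 2.31e-11). The largest decreases were in Hdhd3 (log2 fold change -4.83, SE 0.33), Spata2l (-4.74, SE 0.35), Tlr12, an endosomal Toll-like receptor (-4.52, SE 0.45), Inhbe, an activin subunit made by hepatocytes (-4.18, SE 0.26), and Ccnf, a cyclin (-4.07, SE 0.28). Hdhd3 went from 33.2 ± 10.5 to 1.19 ± 0.633 CPM. Spata2l overlaps Cdk10 on the other strand, so its counts may lack reads of the overlap set aside as ambiguous, or include reads of Cdk10. Adjusted p for these 5 genes lay between 9.07e-10 and 2.93e-07. In the files, Cxcl2 is ENSMUSG00000058427.11, Ccl3 ENSMUSG00000000982.6, Acod1 ENSMUSG00000022126.7, Hdhd3 ENSMUSG00000038422.3 and Inhbe ENSMUSG00000047492.6.

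Cytokine and chemokine genes rose almost throughout. Of 33 tested genes of NF-kB and cytokine signalling, 32 rose and 0 fell, with a median log2 fold change of 4.83. Of 31 chemokines and receptors, 27 rose, and 1 fell, Cxcl12, a chemokine that stromal cells make at rest (log2 fold change -0.97, SE 0.23). Csf3, the growth factor of neutrophils, had no control count and was at least 622.7-fold higher, at 25.0 ± 8.00 CPM. Tnf rose from 0.0840 ± 0.0484 to 33.4 ± 32.1 CPM (log2 fold change 8.53, SE 0.80), Il6 from 0.0911 ± 0.141 to 15.3 ± 6.21 CPM (7.58, SE 0.62; 8.50 without control 4) and Il1b from 1.92 ± 0.609 to 215 ± 99.3 CPM (6.81, SE 0.41). Tnf was at 78.3 and 91.1 CPM in model 7 and model 8, against 10.5 to 21.4 in the other model libraries. The median for chemokines was 4.91. Neutrophil markers rose in the same livers, with a median of 7.79. Camera placed both lists above other genes (adjusted p = 1.76e-32 and 6.52e-24), and both calls held with an estimated correlation (adjusted p = 0.00249 and 0.0042). There were 32 cytokine genes and 28 chemokine genes higher, and 0 and 1 lower, when adjusted over the list alone.

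Over all 34 lists, camera called 16 higher and 0 lower, and 8 held with an estimated correlation. At the preset correlation, 32 of 100 splits of the 14 libraries, the real one included, called at least 16 lists, counted in either direction. Other splits can place the model libraries unevenly, and so carry part of the difference between the groups. The number of such splits therefore does not show whether a count of 16 is usual, and chance is not excluded by it. With an estimated correlation, no other drawn split called a list. These splits mix the groups, so the difference between the groups enters their spread and can raise the estimated correlation. Their lack of calls is therefore no evidence for the 8 lists. The lists whose calls held are those of NF-kB and cytokines, chemokines, interferon, LPS sensing, neutrophils, monocytes, dendritic cells and immediate early genes. Camera's direction for 6 lists without a call turned under at least 1 alternative: galactose and uridine metabolism, hepatocyte identity, Kupffer cells, B cells, sinusoidal endothelium and pancreas.

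**Figure D2:**
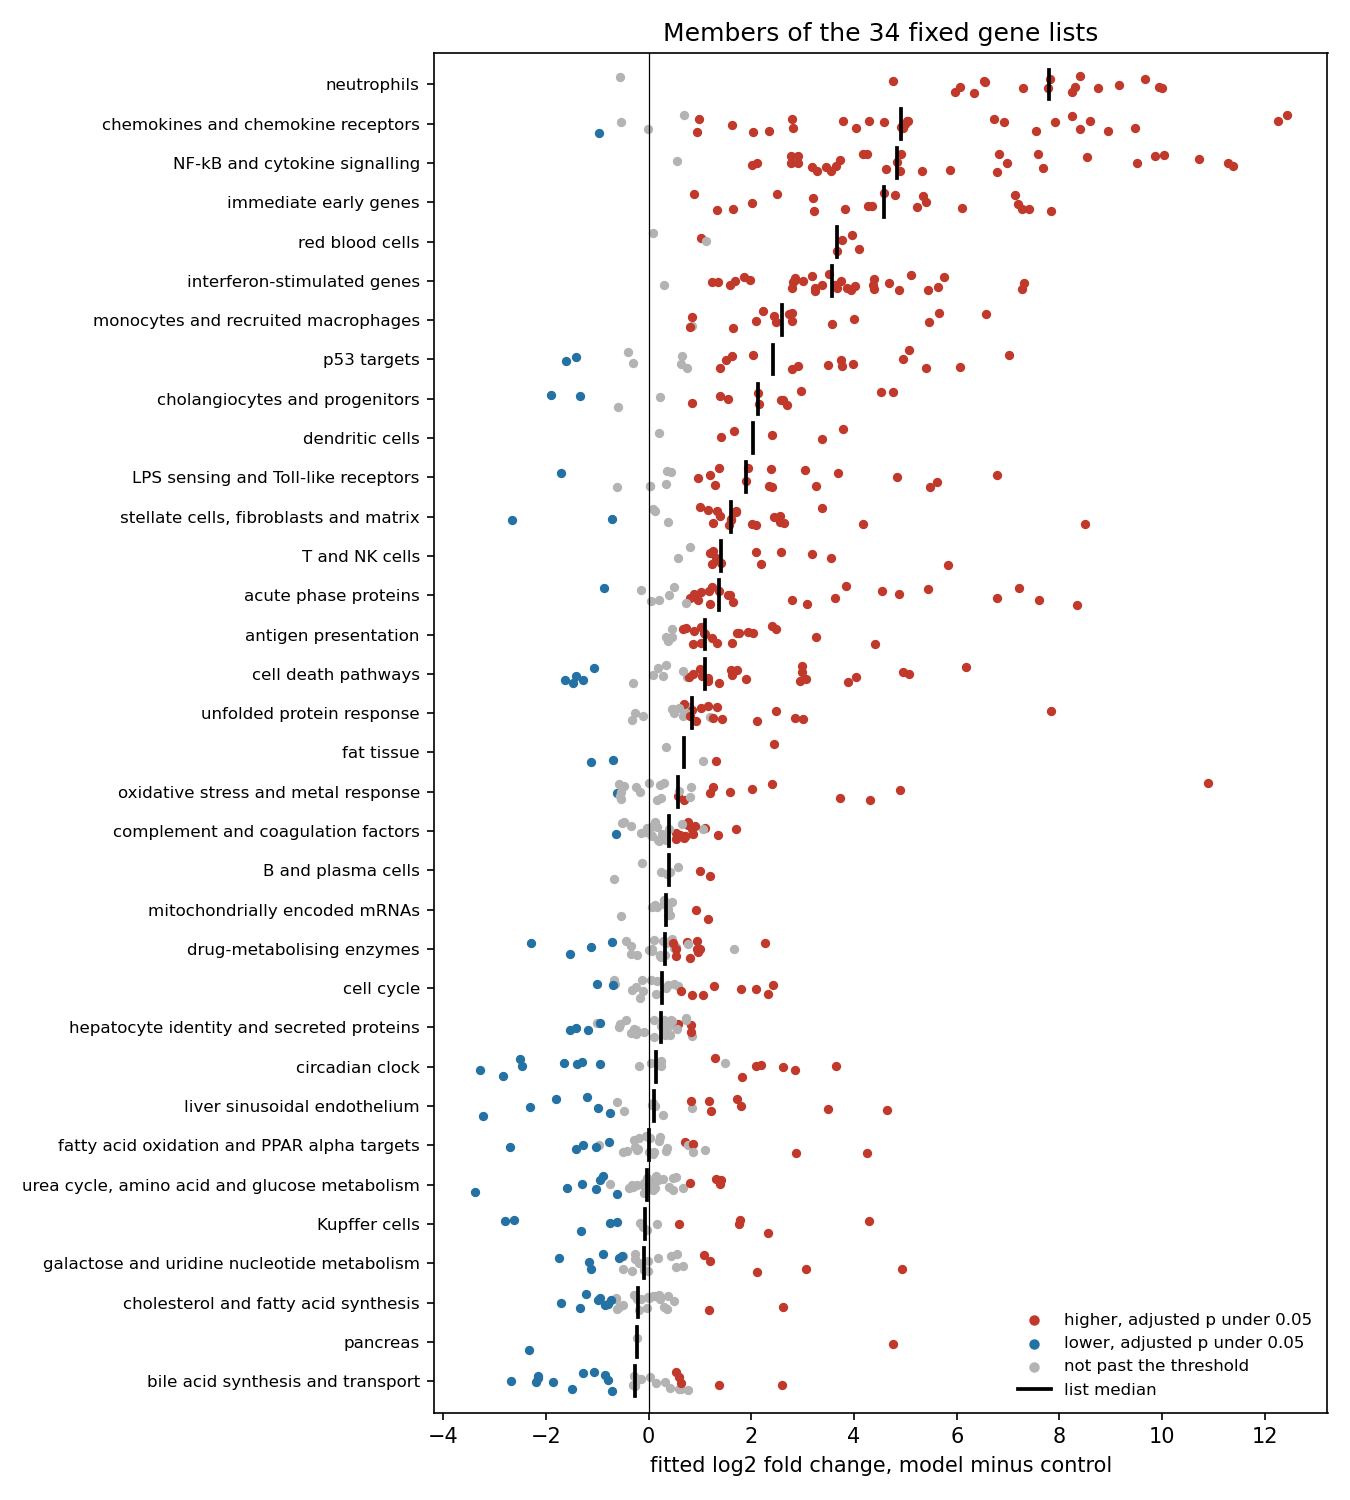
Fitted log2 fold change, model minus control, of each tested member of the 34 lists, 1 point per gene, with the list median as a black bar; red and blue points are genes called higher and lower. The medians run from -0.26 for bile acid synthesis and transport to 7.79 for neutrophils; fitted values of genes without control counts depend on the prior count.

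Interferon-stimulated genes, genes of LPS sensing and Toll-like receptors, and antigen presentation genes rose in most cases. Markers of neutrophils, monocytes and dendritic cells, which are known to express some of these genes, rose in the same livers (medians 7.79, 2.61 and 2.03), and a change in the cells present was not separated from a change within cells. Of 34 interferon-stimulated genes, 33 rose and 0 fell (median 3.57), led by the guanylate-binding proteins Gbp5 (log2 fold change 7.32, SE 0.48) and Gbp2 (7.26, SE 0.31), which went from 3.43 ± 1.04 to 531 ± 147 CPM. Of 23 genes of the list of LPS sensing and Toll-like receptors, 16 rose and 1, the Toll-like receptor Tlr5, fell (log2 fold change -1.71), with a median of 1.89. Tlr12, which fell by 4.52, is not on this list. Cd14, the LPS co-receptor, rose from 1.51 ± 0.410 to 170 ± 70.3 CPM (6.78, SE 0.35), and Irak3, an inhibitor of Toll-like receptor signalling, by 5.62 (SE 0.38). Irak3 overlaps Tmbim4 on the other strand. Of 23 antigen presentation genes, 19 rose and 0 fell (median 1.11), among them the co-stimulator Cd80, from 0.359 ± 0.187 to 7.70 ± 2.32 CPM, and the peptide transporter Tap1 (3.26, SE 0.24), which overlaps Psmb9. Camera gave adjusted p = 2.83e-28, 1.17e-07 and 1.04e-06 for the 3 lists, and with an estimated correlation adjusted p = 0.00623, 0.0123 and 0.0539, so the last call was lost. The counts adjusted over the list alone were 33, 17 and 19 higher and 0, 1 and 0 lower.

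Acute phase genes, which hepatocytes switch on in inflammation, rose in 22 of 29 cases and fell in 1, with a median of 1.37. In the same livers, markers of neutrophils and monocytes rose (medians 7.79 and 2.61). A change in the cells present was not separated from a change within cells. Lcn2, an iron-binding protein of neutrophils and stressed hepatocytes, rose from 4.82 ± 5.98 to 1578 ± 1332 CPM (log2 fold change 8.35, SE 0.90; 9.35 without control 5), Il1rn, the interleukin-1 receptor antagonist, rose by 7.59 (SE 0.39), and Saa1 rose from 167 ± 175 to 2078 ± 1506 CPM (3.64, SE 0.74, adjusted p = 0.000622; 4.41 without control 5). Model 3 and model 4 were at 361 and 106 CPM for Saa1, within the controls' 38.1 to 516, while the other model libraries were at 1421 to 4787, and the mean log2 CPM of the acute phase list was lowest in these libraries among the model livers (8.30 and 8.00 against 9.18 to 10.25). Saa4, a constitutive member of the same family, fell by 0.87 (SE 0.27, adjusted p = 0.0132). Camera's call (adjusted p = 8.75e-06) was lost (adjusted p = 0.429 with an estimated correlation). Of 37 complement and coagulation factors, 15 rose and 1 fell (3 and 5 with library totals), with a median of 0.39 (adjusted p = 0.308; 0.907 with an estimated correlation). The list was called higher with limma-voom (adjusted p = 0.0362), without a low-count filter (0.0337), with the length and GC offset (0.0218) and with fry (0.00613). They included C3, the central complement protein (1.70, SE 0.39), and Pros1, protein S (1.11, SE 0.23), both with CPM ranges that overlap between the groups. Klkb1, plasma prekallikrein, which overlaps Gm45753, fell by 0.63 (SE 0.22, adjusted p = 0.028), and its call was lost without model 7, control 1 or control 6, with adjusted p up to 0.0674. The counts adjusted over the list alone were again 22 and 1 for the acute phase and 15 and 1 for complement and coagulation.

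**Figure D3:**
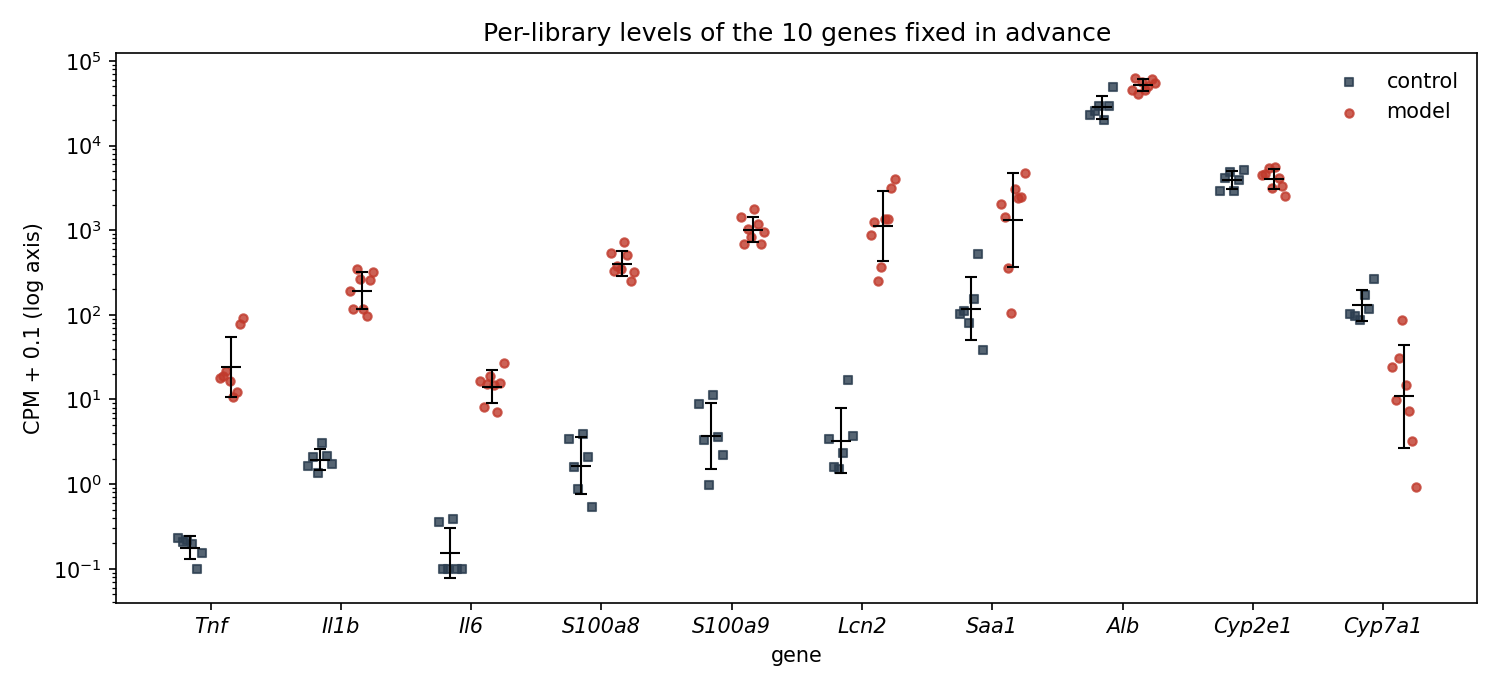
CPM plus 0.1 on a log axis for the 10 genes fixed by name in the 6 control (squares) and 8 model (circles) libraries, 1 point per library; bars show the mean of the log values and 1 SD on the log scale. The ranges of Tnf, Il1b, Il6, S100a8, S100a9, Lcn2 and Cyp7a1 do not overlap between groups, while those of Saa1, Alb and Cyp2e1 do.

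All 21 immediate early genes rose, and the lists of stress and cell death genes had members that rose and members that did not pass. Neutrophil and monocyte markers rose in the same livers (medians 7.79 and 2.61), and cells that arrived were not separated from changes within cells. The 21 immediate early genes had a median of 4.59 (camera adjusted p = 4.01e-22; adjusted p = 0.000513 with an estimated correlation), led by the transcription factor Atf3, which went from 0.687 ± 0.306 to 156 ± 60.7 CPM (log2 fold change 7.84, SE 0.44). Of 25 genes of the unfolded protein response, 14 rose and 0 fell (median 0.84), Atf3 again among them, with Ppp1r15a, a phosphatase subunit that restores translation (3.00, SE 0.20; it overlaps Tulp2). Of 22 p53 targets, 15 rose and 2 fell (median 2.41). The cell cycle inhibitor Cdkn1a (7.03, SE 0.49) and the antiproliferative gene Btg2 (6.06, SE 0.51) rose, and Sesn1 fell by 1.61 (SE 0.20). Of 32 cell death genes, 20 rose and 5 fell (median 1.09). The inflammasome sensor Nlrp3 (6.17, SE 0.55) and the death receptor Tnfrsf10b (5.08, SE 0.75; 5.69 without control 5) rose, while the 5 that fell were the adaptors Tradd (-1.63, SE 0.22) and Fadd, the caspases Casp6 and Casp9, and Bbc3. Tnfrsf10b was at 14.7 and 17.0 CPM in model 7 and model 8, against 1.27 to 4.38 in the other model libraries. Camera called these last 3 lists higher (adjusted p = 0.000629, 0.000659 and 0.00113), and each call was lost (adjusted p = 0.232, 0.164 and 0.0671 with an estimated correlation). Of 27 oxidative stress and metal response genes, 11 rose and 1 fell, against 9 and 5 with library totals (median 0.57; adjusted p = 0.156; 0.618 with an estimated correlation, and called higher with fry, 9.71e-05). Slc7a11, the cystine transporter, had no control count and was at least 474.8-fold higher. The metal-binding protein gene Mt2 rose by 4.90 (SE 0.90), or by 6.70 without control 5, which was at 147 CPM, and Gclm, a subunit of the glutathione-making ligase, fell by 0.61 (SE 0.14). Adjusted over the list alone, the higher and lower counts were 21 and 0 (immediate early), 16 and 0 (unfolded protein), 16 and 3 (p53), 21 and 5 (cell death) and 11 and 1 (oxidative stress).

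Metabolic genes moved in both directions, and none of these lists was called with the settings chosen as main. Of 29 genes of bile acid synthesis and transport, 11 fell and 5 rose (median -0.26; camera adjusted p = 0.0846). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 141 ± 68.7 to 22.1 ± 27.9 CPM (log2 fold change -2.67, SE 0.67, adjusted p = 0.00336; -3.45 without model 4), and Nr1h4, the bile acid receptor, from 118 ± 18.6 to 26.1 ± 2.39 CPM (-2.18, SE 0.15). Abcb11, the bile salt export pump, was higher by 0.64 (SE 0.25, adjusted p = 0.0415), and lost its call without any 1 of model 1, 2, 4, 6 or 7 or control 1, 2, 4 or 5, with adjusted p up to 0.158, without model 3 and model 4 (0.0655), and with library totals (0.313), DESeq2 size factors (0.0547), upper-quartile factors (0.119) or no low-count filter (0.0656). The list itself was called lower without control 1 (adjusted p = 0.0475), with DESeq2 (0.0278), with fry (0.0347) and without a low-count filter (0.0217), over a range of 0.0217 to 0.779 in all alternatives. Of 30 genes of cholesterol and fatty acid synthesis, 8 fell and 2 rose (median -0.20; adjusted p = 0.153; 0.0383 without model 3 and model 4, and 0.0319 without a low-count filter). Thrsp fell by 1.69 (SE 0.48). Acaca, acetyl-CoA carboxylase, fell by 1.33 (SE 0.40), and without control 6 its log2 fold change was -0.62 (adjusted p = 0.0915), while Scd1, a fatty acid desaturase, rose by 1.17 (SE 0.34). Of 30 genes of fatty acid oxidation and PPAR alpha targets, 4 rose and 5 fell. The median and mean were 0.002 and 0.085 and camera's direction was down (adjusted p = 0.594). The lipid droplet protein gene Cidec rose by 4.25 (SE 0.84), although model 3 and model 4 were at 2.88 and 0.453 CPM against 0.636 to 3.18 in the controls, and Pdk4 rose by 2.88 (SE 0.64; 2.20 without model 8), and Cpt1a, which brings fatty acids into mitochondria, fell by 1.41 (SE 0.38), or by 0.86 without control 6. Of 33 genes of the urea cycle, amino acids and glucose, 7 fell and 4 rose (median -0.03; adjusted p = 0.44). G6pc, glucose-6-phosphatase, fell from 158 ± 72.9 to 15.2 ± 9.00 CPM (-3.38, SE 0.50), Nags fell by 1.59 (SE 0.49), and Sds, serine dehydratase, rose by 1.41 (SE 0.35). For G6pc, model 7 and model 8 were at 2.03 and 1.73 CPM (other model libraries 11.7 to 23.1), and for Pdk4 at 35.4 and 70.3 CPM (others 5.09 to 9.86). Nags was at 41.7 and 36.5 CPM in model 7 and model 8, against 2.943 to 15.03 in the other model libraries and 40.8 to 53.3 in the controls. The CPM ranges of the groups also overlap for Thrsp, Acaca, Scd1, Cpt1a and Sds. The higher and lower counts adjusted over the list alone were 5 and 11 (bile acids), 2 and 8 (lipid synthesis), 4 and 5 (oxidation) and 4 and 6 (urea cycle and glucose).

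D-GalN is metabolised through the galactose pathway and ties up uridine nucleotides. Of 25 genes of galactose and uridine nucleotide metabolism, 5 rose and 6 fell. The median was -0.09, the mean 0.27 and camera's direction down (adjusted p = 0.914), while fry called the list higher (0.0328). Upp1, uridine phosphorylase, rose from 2.12 ± 1.12 to 63.6 ± 15.7 CPM (4.94, SE 0.36), while Upp2, the liver form, fell from 417 ± 87.8 to 125 ± 48.3 CPM (-1.74, SE 0.26) and Uck1, uridine kinase, by 1.15 (SE 0.24; it overlaps Pomt1). Of 34 drug-metabolising enzymes, 10 rose and 4 fell (median 0.33; adjusted p = 0.78). Cyp2b10 rose by 2.27 (SE 0.38), Cyp2c54 by 1.01 (SE 0.24), and Cyp2u1 fell by 2.29 (SE 0.33). Cyp2e1, the ethanol-inducible cytochrome, was at 4176 ± 1075 CPM in model and 3979 ± 945 CPM in control (0.07, SE 0.22, adjusted p = 0.807), with a sign that turned negative with library totals or upper-quartile factors and without model 2, control 1 or control 4 (-0.03, -0.01 and -0.01). Of 31 genes of hepatocyte identity and secreted proteins, 3 rose and 4 fell, against 9 and 5 with the length and GC offset (median 0.36) and 1 and 11 with library totals. The median was 0.23, the mean -0.01 and camera's direction down (adjusted p = 0.751). Alb, albumin, rose from 29439 ± 10093 to 52287 ± 8090 CPM (0.83, SE 0.21, adjusted p = 0.00365; 0.0693 with library totals), and the transcription factors Nr1i3 (-1.53, SE 0.40; it overlaps Tomm40l) and Cebpa (-1.41, SE 0.32) fell. Of 24 cell cycle genes, 8 rose and 2 fell (median 0.26; adjusted p = 0.751; called higher with fry, 0.0138). Pcna rose by 0.63 (SE 0.16; adjusted p = 0.0886 with library totals), Rrm2 fell by 0.99 (SE 0.27), and Tyms fell by 0.69 (SE 0.27, adjusted p = 0.0454). The call for Tyms was lost without any 1 of model 4, 6, 7 or 8 or control 1, 2, 4 or 5, with adjusted p up to 0.122, without model 3 and model 4 (0.0592), with the length and GC offset (0.0563), with no low-count filter (0.0605) and with the 20 most abundant genes left out (0.0504). When adjusted over the list alone, these counts were 5 and 6 (galactose and uridine), 10 and 4 (drug metabolism), 3 and 4 (hepatocyte identity) and 7 and 1 (cell cycle).

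The neutrophil list had the highest median of the 9 cell type lists. Of 18 markers tested, 17 rose and 0 fell, with a median of 7.79, or 7.53 with the 1 gene without control counts at its bound (camera adjusted p = 8.68e-37; adjusted p = 8.58e-05 with an estimated correlation). Mmp8, neutrophil collagenase, rose by 9.99 (SE 0.43), and S100a8 and S100a9, the calprotectin subunits, from 1.96 ± 1.35 to 426 ± 156 CPM and from 4.95 ± 4.11 to 1069 ± 376 CPM. Of 16 markers of monocytes and recruited macrophages, 15 rose and 0 fell (median 2.61; adjusted p = 2.11e-12; 0.00802 with an estimated correlation), led by Chil3 (6.58, SE 0.39). Of 6 dendritic cell markers, 5 rose (median 2.03; adjusted p = 0.00632; 0.0472 with an estimated correlation), led by Ccr7 (3.79, SE 0.41), and with DESeq2 the list's adjusted p was 0.0589, in a range over all alternatives from 2.93e-08 to 0.0589. Of 13 T and NK cell markers, 11 rose, led by Gzmb (5.84, SE 0.43), with a median of 1.41 (adjusted p = 0.000449; adjusted p = 0.219 with an estimated correlation). Of 8 B and plasma cell markers, 2 rose, Cd22 and Ighm (1.01, SE 0.30), with a median of 0.39 (adjusted p = 0.78).

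Markers of resident liver cells went both ways. Of 14 Kupffer cell markers, 5 rose and 5 fell, with a median of -0.07, a mean of 0.18 and camera's direction down (adjusted p = 0.751). Marco, a scavenger receptor, rose by 4.30 (SE 0.37), and Slc40a1, the iron exporter, and Cd163, the haemoglobin scavenger receptor, fell (-2.79 and -2.63). Of 20 sinusoidal endothelial markers, 7 rose, led by Lyve1 (4.65, SE 0.27), and 6 fell, among them the pericentral signal Wnt2 and the receptor Kdr (-3.23 and -2.31; median 0.11, adjusted p = 0.751). Of 24 stellate cell and matrix genes, 19 rose and 2 fell (median 1.61; adjusted p = 6.75e-06; adjusted p = 0.143 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 8.50 (SE 0.37), while Lrat, the vitamin A-storing enzyme of quiescent stellate cells, fell (-2.67). Of 15 cholangiocyte and progenitor markers, 11 rose and 2 fell (median 2.12; adjusted p = 0.0227; adjusted p = 0.232 with an estimated correlation), led by Sox9 (4.75, SE 0.60), with Afp among those lower, and the list's call was also lost with the length slope as a covariate (adjusted p = 0.0736). Adjusted over the list alone, the higher and lower counts were 17 and 0 (neutrophils), 16 and 0 (monocytes), 5 and 0 (dendritic), 11 and 0 (T and NK), 2 and 0 (B), 5 and 5 (Kupffer), 7 and 7 (endothelium), 19 and 2 (stellate) and 11 and 3 (cholangiocytes).

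Red blood cell genes were higher in 5 of 7 cases and lower in 0 (median 3.67), without a call for the list (adjusted p = 0.132; 0.8 with an estimated correlation). The list was called higher without model 8 (0.0358), with library totals (0.0489), DESeq2 (0.0159), limma-voom (0.0362), no low-count filter (0.00471) and the length and GC offset (0.0165). Fry, which asks whether the list's genes move one way, called it higher too (0.0127). Hbb-bs, a beta globin, went from 497 ± 346 to 8558 ± 7756 CPM (4.11, SE 0.72). Its group ranges overlapped: model 8 was at 885 CPM and control 1 at 1138 CPM, while model 3 reached 21516 CPM. Of 20 circadian clock genes, 7 rose and 8 fell. The median was 0.14, the mean 0.10 and camera's direction down (adjusted p = 0.39), and Usp2 fell by 3.27 (SE 0.32). Of 12 mitochondrially encoded mRNAs, 2 rose, mt-Co1 (0.93, SE 0.28; 0.58 without model 3 and model 4) and mt-Nd4l. The list's median was 0.34 (adjusted p = 0.751; 0.0463 with the length and GC offset, where 9 rose). Of 6 fat tissue genes, 2 rose, led by Fabp4 (2.44, SE 0.35), and 2 fell (median 0.70; adjusted p = 0.751; called higher with fry, 0.0453). Of 3 pancreas genes, 1 rose and 1 fell, with a median of -0.23, a mean of 0.74 and camera's direction down (adjusted p = 0.78). Cela1 was at 50.4 ± 27.0 CPM in model and 59.0 ± 26.2 CPM in control (-0.23, SE 0.36), not past the threshold and with a positive sign when the length slope was a covariate. The higher and lower counts adjusted over the list alone were 6 and 0 (red blood cells), 8 and 8 (clock), 2 and 0 (mitochondrial), 2 and 2 (fat) and 1 and 1 (pancreas).

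Haemoglobin mRNAs took 0.931% ± 0.777 of counts in model (SD, n = 8) and 0.0681% ± 0.0405 in control (SD, n = 6; exact permutation p = 0.0193, adjusted over 6 classes 0.0573). Model 8, at 0.116%, lay below control 1, at 0.146%. Mitochondrially encoded genes took 11.5% ± 4.37 and 7.60% ± 1.04 (exact p = 0.0286, adjusted 0.0573), and the 10 most abundant genes, led by Alb, mt-Co1 and Apoe, took 21.4% ± 1.86 and 18.6% ± 1.74 (exact p = 0.016, adjusted 0.0573). Major urinary proteins, secreted by male liver, took 4.70% ± 1.07 and 6.70% ± 2.42 (exact p = 0.0539, adjusted 0.0719). Immunoglobulin genes took 0.00366% ± 0.00142 and 0.00254% ± 0.000585 (exact p = 0.0599, adjusted 0.0719). Ribosomal RNA took 2.96% ± 1.87 and 2.15% ± 2.41 (exact p = 0.485). The classes overlap, so their differences are not independent. Mitochondrially encoded ribosomal RNAs count in both the mitochondrial and the ribosomal class. The 10 most abundant genes include mt-Co1, mt-Cytb, Mup3, Mup17 and Rn18s-rs5. None of the 6 classes passed after adjustment, while leaving out model 1, 6, 7 or 8 brought haemoglobin past the threshold (adjusted p = 0.0376, 0.042, 0.042 and 0.0152). Leaving out model 3, with 20.8% mitochondrial counts, took the mitochondrial difference from 3.90 to 2.57 percentage points, and leaving out model 1, 7 or 8 brought it past the threshold (exact permutation, adjusted p = 0.0376, 0.0446 and 0.0105).

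No difference in spread between the model livers and the control livers was detected. The root mean square log2 distance of a library from the rest of its group was 0.646 ± 0.112 in model (SD, n = 8) and 0.596 ± 0.152 in control (SD, n = 6; exact permutation p = 0.483). Without control 5 the difference changed sign (-0.0068, exact p = 0.941).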

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

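The tests of the share of hepatocytes, of more blood and of the unaligned reads, the list of transcription factors, the length and GC offset, the exchanges of single libraries and the splits for lists with an estimated correlation were chosen only after the result was seen. Chance flags about 1 in 20 groups of values, or 8.8 of the 176 examined, and 12 were found with a library far from the others of its group, by Dixon's criterion. Control 2 held 3 of them and control 1 held 2.

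Cxcl2 was at 80.07 CPM in model 6, against 227.7 to 406.8 in the other model libraries, and Slfn4 at 1092 CPM in model 3, against 427.8 to 663. Gzmb was at 6.856 CPM in model 7, against 12.29 to 20.45. Among the controls, Lcn2 was at 16.89 CPM in control 5 (others 1.422 to 3.557), Acod1 at 0.2121 CPM in control 2 (others 0 to 0.05925), and Irak3 at 0 in control 4 (others 0.3854 to 0.7661). Gclm was at 137.8 CPM in control 1 (others 174.6 to 184.3) and Nr1h4 at 155.6 CPM in control 6 (others 105.2 to 115). Haemoglobin mRNAs took 0.1462% of counts in control 1 (others 0.03879 to 0.07389), and immunoglobulin genes 0.006937% in model 4 (others 0.002518 to 0.00383). In control 2 the 10 most abundant genes took 22.09% (others 17.52 to 18.62) and ribosomal RNA 6.943% (others 0.4348 to 1.967). Rn18s-rs5 belongs to both classes, so these flags are not independent.

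Of 100 drawn splits of the 14 libraries into 8 and 6, 1, the real one, called as many as 6188 genes, and the highest other called 0. For changes of at least 2-fold it was again 1, with 4255 genes and a highest other of 0. No other drawn split reached these counts, although splits close to the real one are not empty. A split that mixes the groups puts the difference between them into the spread within groups, which lowers its calls. The drawn splits therefore cannot exclude chance by themselves. Of the 48 exchanges of 1 model library for 1 control library, 22 called any gene, and the most was 4342, for model 5 and control 6. For lists called in either direction, 32 of the 100 splits reached at least the real 16, the highest other called 24 and the median other 14. Such splits can carry part of the difference between the groups, so they can neither show nor exclude chance for that count. With an estimated correlation it was 1 split, with 8 lists against a highest other of 0. Mixing the groups can also raise the estimated correlation, so this cannot exclude chance either.

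Within each group, libraries differed along a gradient with exonic length. The slope of log2 CPM on exonic length correlated with the percent of unaligned reads in the model libraries (r = -0.958, exact permutation p = 0.00057, adjusted over 9 relations 0.00513; rho = -0.881, p = 0.00724, adjusted 0.0326; r = -0.921 without model 2 and model 7). The same held in the controls (r = -0.938, exact p = 0.00556, adjusted 0.025; rho = -1, p = 0.00278, adjusted 0.025; r = -0.966 without control 1 and control 6), so a difference between libraries that also sets alignment, such as RNA integrity or insert length, may lie behind it. Ribosomal RNA as the source stays open (model r = -0.584, exact p = 0.137, adjusted 0.206; rho = -0.667, p = 0.0831; control r = -0.445, exact p = 0.382; rho = -0.829, p = 0.0583), with r = -0.954 without model 3 and model 4 and -0.949 without control 2 and control 6. The slope did not differ between groups past the threshold (0.0398 ± 0.178 in model and -0.0531 ± 0.217 in control, exact permutation p = 0.388), and no biological explanation within a group was tested.

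Haemoglobin mRNAs were higher in model, with a median log2 fold change of 3.86 over 4 genes. The length and GC offset left the median at 4.016, but this could hardly have come out otherwise. Median log2 fold changes ran only from -0.227 for the shortest genes to 0.278 for the longest. The offset had little trend to remove, so its result does not decide on length as a cause. A length trend of that size falls short of the haemoglobin rise of 3.86. More blood of the controls' composition could account for it and cannot be told apart: the B and plasma cell list had an upper quartile of 0.688, but resident B cells can hold its baseline, and in the controls that list was not shown to follow haemoglobin (r = 0.473, exact p = 0.354; rho = 0.257, p = 0.658; r = -0.69 without control 1 and control 3). A link to neutrophil mRNA over the model libraries stays open too (r = 0.312, exact p = 0.441; rho = 0.333, p = 0.428; r = -0.11 without model 1 and model 5), and haemorrhage in the injured liver, part of the difference between the groups, was not tested apart from these. Haemoglobin mRNA was lower where the length slope was higher, without passing adjustment by r (model r = -0.697, exact p = 0.0614, adjusted 0.138; rho = -0.619; r = -0.652 without model 5 and model 7; control r = -0.826, exact p = 0.0431, adjusted 0.129; rho = -0.943, adjusted 0.0501; r = -0.678 without control 3 and control 6).

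Of 38 hepatocyte transcription factors, a list made after the data were seen that shares members with the lists of hepatocyte identity and bile acids, 21 fell and 2 rose (18 fell without control 6, and 7 rose without model 3 and model 4), with a median of -0.92 (camera adjusted p = 0.000183; adjusted p = 0.138 with an estimated correlation). Its p-values are not independent evidence, and were adjusted only over the lists made after the data were seen. Nr1h4, Dbp (-2.84) and Hlf (-2.47) were among those that fell, Cebpb (2.70) rose, and Hnf4a was at 0.84 (adjusted p = 0.0867). A lower share of hepatocytes as the whole cause is argued against by the list of hepatocyte identity and secreted proteins, whose lower quartile of -0.394 lies above that median. With the length and GC offset the median was -0.963 and 25 were lower. The trend with exonic length was too small for the offset to move that median far. This result therefore does not decide on length as a cause, and GC content was not tested apart. Median log2 fold changes ran from -0.227 for the shortest genes to 0.278 for the longest, both smaller in size than -0.92. A slowing of transcription was not tested, because mRNA half-lives were not used here, and all 21 immediate early genes, whose mRNAs are known as short-lived, rose (median 4.59). Markers of neutrophils and monocytes rose in the same livers (medians 7.79 and 2.61), so that rise cannot be assigned to hepatocytes.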

How the results depend on the processing

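Tests with the length and GC offset, the length slope and without model 3 and model 4 were chosen only after the result was seen. Of the 80 named genes, 71 had the same call in every alternative, and of the 34 lists, 11. No gene called in both the main test and an alternative changed direction. Over all alternatives, 2533 to 4441 genes were higher and 2390 to 3955 lower, within 1.5 times the main counts. With other sets of genes tested, DESeq2 called 7837 of 17933 and edgeR without a low-count filter 7358 of 25293. No alternative varied depth, and a gene without a control count is bounded at 0.0401 CPM. The cause of the calls lost for single genes was not tested. The fold of called named genes moved by over 1.5 times for 8 genes with limma-voom, 5 with DESeq2 (in each, 4 had no control count), 6 with the replicate block, 1 with the length slope and 3 without model 3 and model 4 (Cyp7a1 -3.832, Thrsp -2.299 and Hbb-bs 3.505). With limma-voom Cidec was at 3.385 (adjusted p = 0.0244), Tnf at 7.74, Mt2 at 6.27 and Cyp7a1 at -3.644, and Pdk4 was at 2.082 with DESeq2 and 2.28 with the length slope. Counts of list members moved too: with library totals 4 drug-metabolising enzymes rose and 6 fell, 10 galactose and uridine genes fell, 8 fatty acid oxidation genes fell and 2 rose, 12 bile acid genes fell and 2 rose, 11 lipid synthesis genes and 10 of the urea cycle and glucose fell, 4 p53 targets fell and 4 cell cycle genes rose and 3 fell. With the length slope 11 hepatocyte identity genes rose.

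The number of lists higher was 16 in the main test, 8 with an estimated correlation, 22 with fry, 19 with the length and GC offset and 15 to 18 otherwise. The number of lists lower was 1 with DESeq2, 2 without a low-count filter, 1 without model 3 and model 4 and 1 with fry. Leaving out single libraries gave 0 to 1, with 1 without control 1. Camera's directions turned for the galactose and uridine list with the replicate block (adjusted p = 0.924), with the length slope (0.9) and without control 6 (0.978), in a range without single libraries of 0.848 to 0.993. They turned for hepatocyte identity with the offset (0.736), for Kupffer cells with the block (0.775) and the offset (0.908), and for pancreas without a low-count filter (0.947) and with the block (0.72). Without model 3 and model 4 they turned for B cells (0.98) and sinusoidal endothelium (0.995). Fry does not compare a list with other genes, so its direction is not a turn of camera's. It was up for the galactose and uridine (0.0328), hepatocyte identity (0.749) and Kupffer cell (0.958) lists. Cela1 turned to 0.067 with the block and 0.114 with the length slope. Cyp2e1 turned to -0.239 with library totals and -0.087 with upper-quartile factors, and ranged from -0.026 to 0.185 without single libraries, with negative values without model 2, control 1 and control 4.

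Without single libraries, the difference in share of counts ranged from 2.568 to 4.622 percentage points for mitochondrial genes, 0.7189 to 0.9789 for haemoglobin, -2.601 to -1.265 for major urinary proteins, 0.0006471 to 0.001278 for immunoglobulin, 2.331 to 3.511 for the 10 most abundant genes and 0.285 to 1.774 for ribosomal RNA (0.285 without model 3 and 1.774 without control 2). Each but ribosomal RNA passed adjustment in at least 1 of these fits: urinary proteins without model 1 (exact permutation, adjusted p = 0.0376), immunoglobulin without model 7 (0.0446) and the 10 genes without model 1, 7, 8 or control 2 (0.0152 to 0.0446). The difference in spread ranged from -0.006801 to 0.09611, reversed without control 5.

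The replicate numbers were not shown to pair the libraries: same-numbered deviations correlated at 0.363, -0.282, -0.342, -0.005, -0.037 and -0.103. The block took the calls from 6188 to 5375, 2985 higher and 2390 lower, and ended those of Klkb1, Abcb11, Acaca, Tyms and Sds (adjusted p = 0.0976, 0.0541, 0.161, 0.104 and 0.0579). It moved Pdk4 to 1.76, Nags to -2.82, Cidec to 2.977 (adjusted p = 0.0161), Tnf to 7.484, Mt2 to 6.003 and Tnfrsf10b to 3.978, and the red blood cell list was called higher with it (adjusted p = 0.000177).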

Other observations

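The lists here and the test of cytokine against acute phase mRNA were chosen only after the result was seen, so their counts and p-values are not independent evidence of direction. Camera's p-values here were adjusted only over the lists made after the data were seen. Neutrophil and monocyte markers rose in the same livers (list medians 7.79 and 2.61), and each of the first 3 lists here holds genes known to be expressed by such cells. These are Plaur, Ptafr and F13a1 for clotting, Hk3 and Slc2a3 for glycolysis, and Mmp8, Mmp9 and Adam8 for proteases, and Mmp8 and Mmp9 are also on the neutrophil list. A change in the cells present and a change within cells are not separated here. Regulators of clotting and fibrinolysis rose in 13 of 17 cases and fell in 0, with a median log2 fold change of 2.91 (camera adjusted p = 1.2e-14; adjusted p = 0.000274 with an estimated correlation). Thbs1, thrombospondin, rose by 9.34 (SE 0.58), and Procr, the protein C receptor, by 6.56 (SE 0.37). The inhibitors Tfpi and Tfpi2 did not pass (0.25 and -0.34). Of 37 complement and coagulation factors themselves, 15 rose and 1 fell, with a median of 0.39.

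Genes of the hypoxia response and glycolysis rose in 19 of 24 cases and fell in 2 (median 2.59; camera adjusted p = 3.07e-12; adjusted p = 0.000274 with an estimated correlation). Slc16a3, a lactate exporter, rose from 0.160 ± 0.0880 to 43.8 ± 5.80 CPM (7.93, SE 0.31), Pkm, the muscle-type pyruvate kinase, by 4.14 (SE 0.23), and Hif1a by 2.72 (SE 0.32). Bnip3, a target of that factor, fell by 1.75 (SE 0.27), and Pgk1 and Ldha did not pass (0.23 and 0.45). Matrix proteases and inhibitors rose in 14 of 15 cases (median 4.50; camera adjusted p = 5.5e-19; adjusted p = 0.000274 with an estimated correlation), among them the collagenase Mmp13 (7.86, SE 0.57) and Adamts4 (8.29, SE 0.53), and Mmp19 fell by 0.74. Of 30 secreted proteins of hepatocytes, 8 rose and 0 fell (median 0.33; adjusted p = 0.357), against 15 and 0 with the length and GC offset (median 0.49) and 3 and 4 with library totals, among them Trf, transferrin (0.97, SE 0.17).

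A hypothesis was that cytokine mRNA may fall as acute phase mRNA rises over the model libraries. The correlation of the list means was positive (r = 0.603, exact permutation p = 0.114, adjusted over 9 relations 0.205; rho = 0.548, p = 0.171, adjusted 0.22), opposite in sign to the hypothesis, and rested on model 7 and model 8 (r = 0.099 without them), so it stays open.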
